A study of Mus musculus with 28 samples.

How the data were processed

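The series holds bulk RNA sequencing of mouse hippocampus and RNA immunoprecipitation (RIP) libraries. Per the labels, polyadenylated hippocampal RNA was sequenced from animals 9 months of age in 2 cohorts, each with its own WT and 5xFAD animals. The 5xFAD line is a transgenic model of Alzheimer's disease in which neurons express mutant human transgenes, APP among them, from the Thy1 promoter. The Ripk1 cohort adds Ripk1 D138N, a mutation that removes the kinase activity of RIPK1, without and with the 5xFAD transgenes. The Zbp1 cohort adds Zbp1 knockout (KO) animals in the same way. Each genotype has 3 libraries, so each cohort has 12 and the series 24 hippocampal libraries. The 4 RIP libraries are an input and a ZBP1 immunoprecipitate (IP) from WT and the same pair from 5xFAD, with 1 library each. Groups were taken from the sample titles.

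For the hippocampus the authors deposited 1 table per cohort of counts, whole numbers of reads per Ensembl gene ID. Per the submitters' processing notes the tools included HISAT2, DESeq2 1.42.1 and edgeR 4.0.16, and the builds named are mm10 (GRCm38) and mm39 (GRCm39), with no statement of which step used which. For that reason no coordinates are given. The counting options, and whether strand was used, are not given in the sources used here, so reads of overlapping genes and of near-identical copies could have been split between them. The authors also deposited tables of their own comparisons, which hold log2 fold changes, a p-value and an adjusted p-value per gene and a call, per the file headers. Heat-map tables hold a scaled score per gene and library, per the file headers. Those scores served only to check library names: in each cohort the 12 libraries correlated best with the count column of their own name. For the RIP libraries the authors deposited 1 count table whose entries are gene symbols and repeat families, and tables of comparisons with log2 fold changes, p-values and calls, per the file headers.

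Everything else was computed here. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Each count table lists 55487 gene IDs, of which 55141 matched a symbol in the reference table of gene names, and 16018 had no count in any hippocampal library. No read was counted on mitochondrially encoded genes, so that list could not be tested. Within each cohort the 12 libraries were fitted together in edgeR (TMM normalisation, filterByExpr by genotype, a quasi-likelihood fit with 1 mean per genotype), because 3 libraries per genotype give little information on spread alone. This left 21376 genes in the Ripk1 cohort and 21274 in the Zbp1 cohort. A gene was called when its Benjamini-Hochberg adjusted p lay under 0.05. The standard error (SE) of a log2 fold change is its absolute value divided by the square root of the F statistic. CPM are counts scaled to library size after TMM, given as mean ± SD over 3 libraries; CPM of single libraries are without TMM. The contrasts were 5xFAD against WT, mutant 5xFAD against 5xFAD, mutant against WT, mutant 5xFAD against mutant, and their interaction, which is the 5xFAD effect on the mutant background minus that on the WT background. A fit of all 24 libraries on 22565 genes tested whether the 5xFAD effect differed between cohorts. The labels do not say that libraries of a genotype came from separate animals, so the p-values measure the spread between these libraries. Replicate pairs of a genotype differed by more than sampling noise (chi-square per degree of freedom 7.8 to 87.5), so none was the same library deposited again.

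The comparisons, the 31 gene lists, the rule for named genes and the other settings to be tried were fixed before the data were examined. The inflammatory and glial lists are disease-associated microglia, homeostatic microglia, complement, the type I interferon response, antigen presentation, inflammatory cytokines and NF-kB targets, necroptosis, apoptosis and pyroptosis, reactive astrocytes, astrocyte markers, lysosome, myelin and oligodendrocytes, disease-associated oligodendrocytes and oligodendrocyte precursors. The neuronal and metabolic lists are synapse, inhibitory interneurons, activity-regulated immediate early genes, hippocampal subfields, oxidative phosphorylation and cholesterol synthesis. Lists for other cells or neighbouring tissue are endothelial and mural cells, fibroblasts and meninges, choroid plexus, T and NK lymphocytes, peripheral myeloid cells, red blood cells, thalamus and habenula, neocortex and subiculum, and striatum. Sex-linked markers and a list of targets and transgene-related genes complete the set. Each list was tested with camera (limma) at a preset inter-gene correlation of 0.01, with adjustment over the lists of a contrast, and again with the correlation estimated from the data. Unless stated otherwise, a list is said to be higher or lower when both settings passed the threshold. Members were also counted with p adjusted over the list alone. Genes called in 5xFAD of one cohort were tested as lists in the mutant contrast of the other cohort, so that no list was chosen on the libraries it was tested in.

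Named genes were taken by rule. In each contrast these are up to 8 called genes per direction with the largest log2 fold change, an average of at least 1 log2 CPM and no overlap between the libraries of the groups compared, up to 4 members with the smallest p per list, and targets such as Zbp1, Ripk1, App and Thy1. Results for some genes are not reported here. The RIP libraries have no replicates, so no test was run and no p-value is given. The ratio of IP to input is the log2 ratio of CPM of the whole library, repeats included, with a prior count of 2, for genes with at least 20 counts in IP and input together in each genotype. The RIP named genes are the 8 highest and 4 lowest with at least 100 such counts. Exact 95% conditional binomial intervals cover counting error only. A list's median ratio was placed among those of 10000 random lists of the same size matched on mean expression, which describes these libraries only.

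The computations were tested on simulated data: counts were drawn from the real means and library sizes with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were taken from those with an average of at least 1 log2 CPM, and each gene was drawn on its own. The shares called below therefore do not cover genes under that level. The random lists do not test variation that genes of a library share. For Ripk1 D138N 5xFAD against 5xFAD (20894 genes) 83% of the 2-fold and 99% of the 4-fold changes were called, with 7 false calls. For Zbp1 KO 5xFAD against 5xFAD (20689 genes) the shares were 74% and 96%, with 6 false calls. In each simulation 0 genes were called in the unchanged contrast, and 4 and 3 of 100 random lists were called. The other settings were DESeq2 size factors, DESeq2 in place of edgeR, no filter beyond a total count of 1, the replicate number as a block, only the libraries of the 2 groups compared, and each library left out in turn. For the RIP libraries these were another prior count (0.5), TMM factors and a minimum of 100 counts. Added after the data were seen were the Thy1 level or the choroid plexus score of each library as a covariate, the removal of a pair of libraries with low Malat1, the difference between cohorts of the mutant effect, and the repeat families of the RIP table.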

Results

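Hippocampal RNA was compared between WT, 5xFAD, mutant and mutant 5xFAD mice in 2 cohorts with 3 libraries per genotype, 24 libraries in all. Library size ran from 16.6 to 44.8 M counts in the Ripk1 cohort. In the Zbp1 cohort it ran from 8.4 M (WT 1) to 34.6 M, and the next lowest library had 27.1 M. Between libraries of a cohort, correlations of log2 CPM ran from 0.9592 to 0.989 (Ripk1) and from 0.9347 to 0.9807 (Zbp1). All 24 libraries showed a male pattern, with Ddx3y (a Y-linked gene) at 63.39 to 89.67 CPM and Xist at 0.14 to 3.51 CPM. Some libraries stood apart by 1 gene or more. In the Ripk1 cohort 5xFAD 1 had 532.05 CPM of Fos, an immediate early gene induced by neuronal activity, where no other library passed 25.11. In the Zbp1 cohort WT 2 and 5xFAD 2 had 968.74 and 782.46 CPM of the nuclear RNA Malat1 against 1937.72 to 2977.94 in all other libraries of the series. The same 5xFAD 2 had 53.69 CPM of Prox1, a gene of dentate gyrus neurons, against 112.96 to 179.17 elsewhere. Cst7, a gene of plaque-associated microglia, was at 4.66 CPM in WT 1 of that cohort against 0.12 and 0.34 in the other WT libraries. The 5xFAD libraries there had 114.2, 106.05 and 49.1 CPM of Cst7 and 2216.58, 2018.04 and 1477.51 CPM of Thy1, with 5xFAD 3 lowest in each. Ttr, a choroid plexus gene, ran from 17.17 to 4369.13 CPM, so libraries held different amounts of that neighbouring tissue.

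Zbp1, the sensor of Z-form nucleic acids whose product recruits RIPK1 and RIPK3, was nearly silent in WT hippocampus and rose in 5xFAD. In the Ripk1 cohort it was at 0.192 ± 0.0842 CPM in WT, 6.01 ± 1.96 in 5xFAD, 0.101 ± 0.0333 in Ripk1 D138N and 1.06 ± 0.288 in Ripk1 D138N 5xFAD. Its log2 fold change was 4.94 ± 0.41 in 5xFAD against WT (edgeR, adjusted p = 2.99e-06) and 3.33 ± 0.47 in Ripk1 D138N 5xFAD against Ripk1 D138N (adjusted p = 0.000762). Ripk1 D138N 5xFAD against 5xFAD gave -2.51 ± 0.34 (edgeR, adjusted p = 0.00537; -2.29 and 0.0501 without Ripk1 D138N 5xFAD 3). In the Zbp1 cohort the gene was at 0.161 ± 0.199 CPM in WT, 2.41 ± 1.01 in 5xFAD, 0.106 ± 0.184 in Zbp1 KO and 0.323 ± 0.0264 in Zbp1 KO 5xFAD. These levels are near the limit of counting: 0 to 12 counts in WT, 52 to 125 in 5xFAD, 0 to 11 in KO, with all 11 in KO 3, and 9 to 11 in KO 5xFAD. The 5xFAD effect on Zbp1 (3.59 ± 0.96) was not called by edgeR (adjusted p = 0.0619), though it was without WT 2 (4.96) or without 5xFAD 2 (3.76). Zbp1 KO 5xFAD against 5xFAD had a point estimate of -2.89 ± 0.88 and no call (edgeR, adjusted p = 0.446). Remaining Zbp1 reads in KO animals show only that part of the transcript is still counted, not that protein is made.

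Ripk1, which encodes a kinase of death receptor and ZBP1 signalling, was modestly higher in 5xFAD carriers and little changed by either mutation. In CPM every carrier library lay above every non-carrier library of its cohort, also on the mutant backgrounds. In the Ripk1 cohort Ripk1 was at 7.6 ± 0.755 CPM in WT, 10.2 ± 0.552 in 5xFAD, 7.72 ± 1.05 in D138N and 10.1 ± 0.424 in D138N 5xFAD. The difference between D138N 5xFAD and 5xFAD was -0.01 ± 0.13 (edgeR, adjusted p = 0.991), as a point mutation of the kinase domain need not alter RNA level. Its 5xFAD effect there (0.42 ± 0.13, edgeR, adjusted p = 0.0454) was called only with all libraries and was lost whichever library was left out (0.36 to 0.49). In the Zbp1 cohort the effect was 0.7 ± 0.2 (edgeR, adjusted p = 0.0909; 0.79 and 0.0474 without 5xFAD 2), at 6.93 ± 1.36 CPM in WT, 11.2 ± 1.61 in 5xFAD, 6.53 ± 0.89 in Zbp1 KO and 9.78 ± 1.06 in Zbp1 KO 5xFAD. Thy1, whose promoter cassette drives the transgenes, was higher in 5xFAD by 2.12 ± 0.12 (Ripk1 cohort, adjusted p = 1.33e-07) and 1.61 ± 0.13 (Zbp1 cohort, adjusted p = 1.21e-05). In CPM it was at 570 ± 34.8 in WT, 2475 ± 234 in 5xFAD, 564 ± 33.2 in D138N and 1862 ± 342 in D138N 5xFAD, and in the Zbp1 cohort at 616 ± 69.2, 1887 ± 373, 533 ± 27.9 (KO) and 1512 ± 62 (KO 5xFAD). With all libraries edgeR did not call Thy1 between 5xFAD groups. For Ripk1 D138N it was at -0.41 ± 0.12 (edgeR, adjusted p = 0.234, or -0.58 and 0.0113 without Ripk1 D138N 5xFAD 2). For Zbp1 KO it was at -0.32 ± 0.13 (edgeR, adjusted p = 0.526). In the Ripk1 cohort, however, Thy1 CPM did not overlap, with at least 2295 in 5xFAD and at most 2251 in D138N 5xFAD. The authors' deposited table of 5xFAD over Ripk1 D138N 5xFAD lists Thy1 at 0.41 with an adjusted p of 0.0344. Their table of 5xFAD over Zbp1 KO 5xFAD lists 0.32 and 0.247. Mouse App (-0.11 ± 0.07 and -0.14 ± 0.08) was not called in 5xFAD of either cohort.

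In 5xFAD of the Ripk1 cohort, genes of activated microglia and of the interferon response were among the most raised. Cst7 went from 0.17 ± 0.1 to 60.5 ± 12.5 CPM (log2 fold change 8.42 ± 0.28, edgeR, adjusted p = 2.55e-09), Itgax went from 0.291 to 30.6 CPM (6.69 ± 0.31, 3.7e-08) and Clec7a rose by 5.52 ± 0.36 (4.53e-07), each without overlap of the 3 and 3 libraries. Cxcl10, an interferon-induced chemokine, rose by 6.02 ± 0.43 and Mx1, an antiviral GTPase, by 6.16 ± 0.6 (adjusted p = 8.08e-07 and 1.45e-05). Of 29 genes of disease-associated microglia 27 were higher and 2 not called (median 2.06), and of 20 homeostatic microglial genes 15 were higher, 1 lower and 4 not called (median 1.04, 17 higher with p adjusted over the list alone). Csf1r (1.34 ± 0.09), which all microglia express, was among the latter. All 39 genes of the type I interferon response were higher (median 2.94, Isg15 3.25 ± 0.22, Ifit1 3.97 ± 0.26, Irf7 3.92 ± 0.27), as were 21 of 22 genes of antigen presentation (median 2.6, B2m 2.58 ± 0.21) with 1 lower. Complement had 11 of 19 higher (12 adjusted over the list alone, C1qa 2.81 ± 0.16, C4b 2.96 ± 0.12), inflammatory cytokines and NF-kB targets 16 of 25 (18, Tlr2 2.81 ± 0.19) and lysosome 23 of 30 (25, Ctss 2.71 ± 0.14). Necroptosis, apoptosis and pyroptosis had 13 of 26 higher and 2 lower (15 and 2 adjusted over the list alone), among them the pore-forming Gsdmd (1.61 ± 0.17) and the TNF receptor Tnfrsf1a (1.52 ± 0.13).

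Glia other than microglia changed in narrower ways. Among 27 reactive astrocyte genes 15 were higher (18 adjusted over the list alone; median 1.48), with Gfap at 2.69 ± 0.15 and the protease inhibitor Serpina3n at 2.39 ± 0.14. The 15 general astrocyte markers went in opposite directions, with 6 higher (Aqp4 0.84 ± 0.13), 2 lower (Fgfr3 -0.39 ± 0.07) and 7 not called, and the list was not called (adjusted p = 0.24). Disease-associated oligodendrocyte genes had 6 of 11 higher (7 adjusted over the list alone; median 0.77). The myelin list had 7 of 20 higher (11 adjusted over the list alone; median 0.32, Trf 0.93 ± 0.18), but its call at the preset correlation was lost with an estimated one (adjusted p = 0.421). Among oligodendrocyte precursor genes 1 was higher and 1 lower of 10 (adjusted p = 0.755). Cholesterol synthesis had 12 of 24 higher (16 and 1 lower adjusted over the list alone, Mvd 1.04 ± 0.18, Fdft1 0.69 ± 0.1, adjusted p = 0.173 with an estimated correlation). Oxidative phosphorylation had 11 of 41 higher (15 adjusted over the list alone, Uqcrq 0.52 ± 0.12, adjusted p = 0.454 with an estimated correlation).

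Single neuronal genes were lower in this contrast, but no neuronal list was lower with an estimated correlation. Slc17a6, the vesicular glutamate transporter of subcortical and subicular neurons, fell from 29.4 ± 8.79 to 7.64 ± 2.19 CPM (-1.93 ± 0.35, edgeR, adjusted p = 0.00293), as did Mme, which encodes the amyloid-degrading enzyme neprilysin (-1.8 ± 0.34, 0.00375). Exph5 (-1.57 ± 0.27, 0.00203) and the protocadherin Pcdh11x (-1.49 ± 0.23, 0.000862) were lower too. Of 35 synapse genes 16 were lower and 19 not called (21 lower and 2 higher adjusted over the list alone, Shank1 -0.48 ± 0.09, Dlg2 -0.54 ± 0.09, Syt1 -0.44 ± 0.09), at a list median of -0.3 whose call ended with an estimated correlation (adjusted p = 0.198). Inhibitory interneuron genes had 5 of 15 lower (7 adjusted over the list alone, Gad1 -0.65 ± 0.13, adjusted p = 0.235 with an estimated correlation) and neocortex and subiculum 3 of 14 (6, adjusted p = 0.235 with an estimated correlation). Hippocampal subfield genes had 1 higher and 1 lower of 17 (adjusted p = 0.502). Activity-regulated immediate early genes had 7 of 21 higher (13 and 2 lower adjusted over the list alone; adjusted p = 0.0536). This came from 1 library: without 5xFAD 1, Fos went from 4.49 ± 1.2 (0.0215) to 0.64 (0.476) and Junb from 2.21 ± 0.64 (0.0318) to 0.34 (0.202).

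Markers of other cells and of neighbouring tissue mostly stayed level in the same contrast. T and NK lymphocyte genes were the exception, with 7 of 13 higher (8 adjusted over the list alone, median 1.6, Cd3g 3.98 ± 0.83, Cd5 3.25 ± 0.68, edgeR, adjusted p = 0.00596 and 0.00643). Both were near the limit of counting, with Cd3g at 0.905 ± 0.565 CPM in 5xFAD and 0.0528 ± 0.0553 in WT. Cd5 was at 0.867 ± 0.139 and 0.0906 ± 0.0785. Peripheral myeloid genes had 1 of 15 higher (adjusted p = 0.478), endothelial and mural genes 2 of 20 (Ly6c1 0.49 ± 0.11, adjusted p = 0.204), and thalamus and habenula 2 of 12 lower (adjusted p = 0.123). No member was called by edgeR among fibroblast and meningeal (adjusted p of the list = 0.786), choroid plexus (0.646), red blood cell (0.825) and striatal genes (0.24). Of 6 sex-linked markers Ddx3y was lower (-0.28 ± 0.07, edgeR, adjusted p = 0.0132, not called without WT 1) and the list was not called (0.381). In the list of targets and transgene-related genes 3 of 7 were higher. Over all genes edgeR called 1734 higher and 1715 lower of 21376, of which 709 and 106 by at least 2-fold; DESeq2 called 4284. The total of 3449 was 1823 without WT 1 and 1757 without 5xFAD 2.

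Genes of activated microglia were again among the most raised in 5xFAD of the Zbp1 cohort. Cst7 was at 89 ± 35.1 CPM against 1.72 ± 2.58 in WT (6.54 ± 0.79, edgeR, adjusted p = 0.000204), and Itgax rose by 5.64 ± 0.71 (0.000258). Trem2, the receptor needed for the plaque response, rose by 3.23 ± 0.24 (7.25e-06) and the MHC class II chain Cd74 by 4.76 ± 0.57 (0.000175). Disease-associated microglia had 25 of 29 genes higher (27 adjusted over the list alone; median 1.8), homeostatic microglia 12 of 20 (16, median 1.17), antigen presentation 18 of 22 (19, median 2.02) and the type I interferon response 26 of 39 (37, median 1.74, Oasl2 2.64 ± 0.22). Reactive astrocytes had 13 of 27 higher (15 adjusted over the list alone, Gfap 2.46 ± 0.17) and lysosome 23 of 30 (25). Complement had 11 of 19 (11, C4b 2.58 ± 0.16), disease-associated oligodendrocytes 6 of 11 (8) and cell death 6 of 26 (15, Nlrp3 2.3 ± 0.38, Gsdmd 1.44 ± 0.23). T and NK lymphocyte genes were higher as a list, with 1 of 12 called (3 adjusted over the list alone, median 1.16, adjusted p = 0.015 with an estimated correlation). Cd3g was near the limit of counting here too, at 0.494 ± 0.18 CPM in 5xFAD and 0.0223 ± 0.0386 in WT. Among the neuronal genes that were lower, the calls of the glutamate receptor Grm8 (-1.04 ± 0.2, edgeR, adjusted p = 0.00687) and of Cacng3 (-0.58 ± 0.11, 0.00725), an auxiliary protein of AMPA receptors, stood whichever library was left out. Slc17a6 was lower here too (-1.42 ± 0.35, edgeR, adjusted p = 0.0368), a call lost without any 1 library except WT 2 (-1.28 to -1.61). Of 35 synapse genes 1 was lower (4 adjusted over the list alone; median -0.2, adjusted p = 0.0806 with an estimated correlation). edgeR called 638 genes higher and 27 lower of 21274, DESeq2 1034 in all (898 and 136). The 665 were 413 without 5xFAD 1, with 6 lower, and 1103 without 5xFAD 2, with 332 lower.

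The cohorts shared most of the genes called in the smaller set. Among 20680 genes tested in each, 537 were higher in both, of 1714 and 636, where 52.7 would be shared by chance, and 12 were lower in both, of 1712 and 27 (2.24 by chance). Whether the 5xFAD effect differed between cohorts was tested on 22565 genes: edgeR called 0, with 2063 at unadjusted p under 0.05 and 26 called by DESeq2 (593 by edgeR without 5xFAD 2 of the Zbp1 cohort). Among the smallest p were Ifit1 (1.97 ± 0.41 larger in the Ripk1 cohort) and Mx1 (3.72 ± 0.77), each with adjusted p = 0.237. As a list the type I interferon response was more raised in the Ripk1 cohort (median difference 0.98, 16 of 39 with p adjusted over the list alone; adjusted p = 0.0357 with an estimated correlation). Cohort and any handling that went with it cannot be separated here.

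In 5xFAD mice with kinase-dead Ripk1 the interferon response was lower than in 5xFAD, while most of the microglial activation genes were not called. Ifit1 fell from 36.1 ± 11.8 to 5.5 ± 0.358 CPM (-2.71 ± 0.25, edgeR, adjusted p = 0.000383). Irf7, the transcription factor that amplifies interferon production, fell from 24.3 ± 6.31 to 3.81 ± 0.769 (-2.67 ± 0.25, 0.000383) and Isg15 from 11 ± 2.29 to 2.09 ± 0.413 (-2.4 ± 0.21, 0.000383), with no overlap between the 3 and 3 libraries. Oasl2 (-2.48 ± 0.27, 0.00139), the GTPase Iigp1 (-2.31 ± 0.28, 0.00221) and the MHC class Ib gene H2-T23 (-1.29 ± 0.15, 0.00216) fell with them, and these calls stood whichever library was left out. With the Thy1 level of each library as a covariate, however, 0 of the 78 calls of this contrast remained. The median of the 39 interferon genes was -1.48 instead of -1.72 and the median SE of a member 0.42 instead of 0.27. At unadjusted p under 0.05 (edgeR) 37 of these 39 genes remained, against 39 without the covariate. Of 39 interferon response genes 30 were lower (39 adjusted over the list alone; median -1.72, adjusted p = 0.000574 with an estimated correlation), and of 22 genes of antigen presentation 8 were (21 adjusted over the list alone; median -1.3). Inflammatory cytokines and NF-kB targets had 2 of 25 lower (10 adjusted over the list alone; median -0.54). Complement, with 0 of 19 called by edgeR (4 lower adjusted over the list alone), and T and NK lymphocyte genes were lower as lists (medians -0.33 and -0.77, adjusted p = 0.0345 each with an estimated correlation).

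Disease-associated microglial genes had a median of -0.18 in that contrast, with 0 of 29 called even over the list alone. The list call at the preset correlation was lost with an estimated one (adjusted p = 0.358) and without 5xFAD 3 (-0.12). Homeostatic microglial genes (median -0.12, 4 lower and 1 higher of 20 adjusted over the list alone; adjusted p = 0.221 with an estimated correlation), lysosome (-0.13, 3 lower, 0.221) and reactive astrocytes (-0.35, 7 lower, 0.0797) were not lower at that setting either. Necroptosis, apoptosis and pyroptosis had 1 of 26 lower (median -0.24, 0.14). C1qa was at -0.63 ± 0.15 (edgeR, adjusted p = 0.151; -0.9 and 0.00189 without Ripk1 D138N 5xFAD 2). Synapse genes (median 0.14, adjusted p = 0.433 with an estimated correlation) and myelin genes (0.16, 0.507) were not called. In all, edgeR called 5 genes higher and 73 lower of 21376, 62 of the latter by at least 2-fold. DESeq2 called 278, of which 130 were higher and 148 lower. The 78 were 43 without 5xFAD 1, 20 without Ripk1 D138N 5xFAD 1, 673 without Ripk1 D138N 5xFAD 2 and 14 without Ripk1 D138N 5xFAD 3, so the number of genes depends on single libraries. Of the 673, 348 were higher and 325 lower, and without a filter edgeR called 195 higher and 192 lower. The balance of directions therefore depends on the fit too. All 73 lower genes were among the 1734 higher in 5xFAD (5.92 by chance for independent groups). These contrasts share the 5xFAD libraries, and simulations without any genotype effect, which gave 0, do not test this overlap. Against an outside list, 55 of the 73 were also among the 636 genes higher in 5xFAD of the Zbp1 cohort (2.25 by chance).

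**Figure D1:**
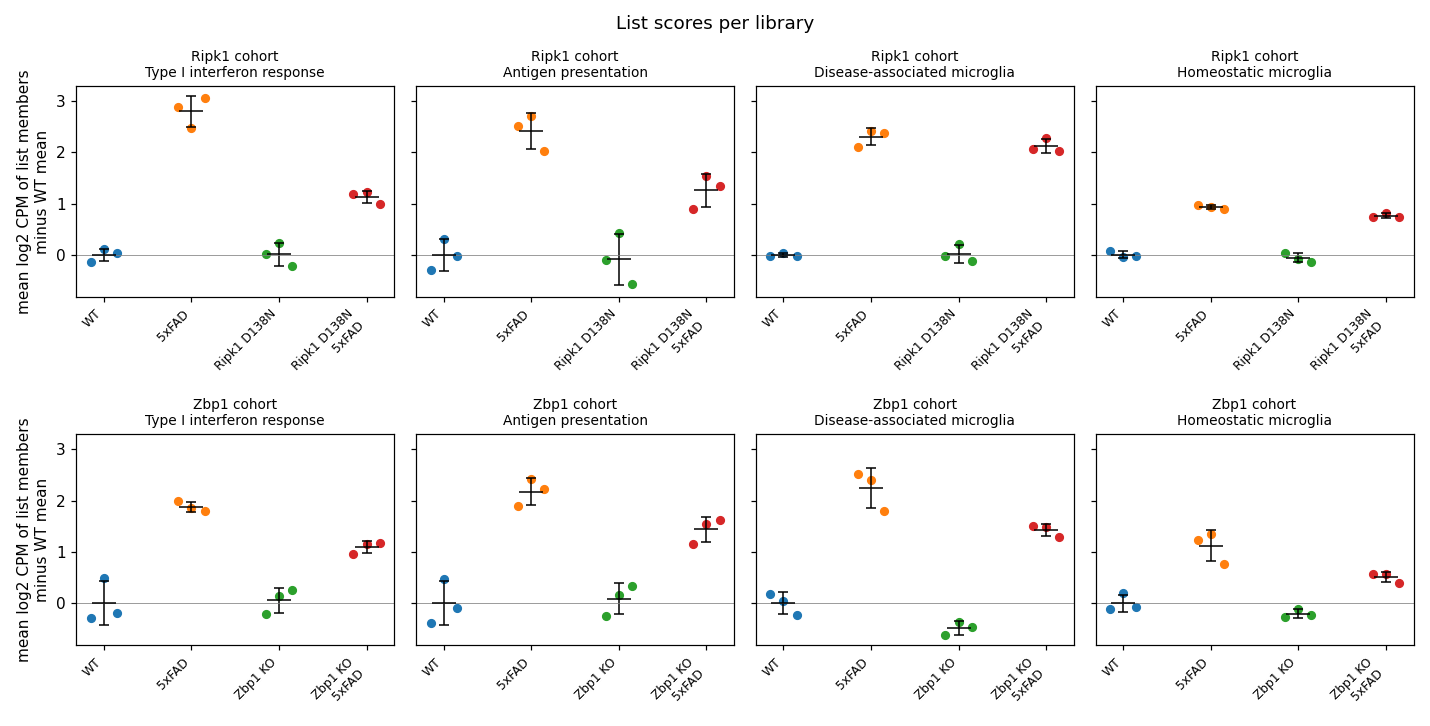
Mean log2 expression of the members of 4 gene lists in each of the 24 libraries, relative to WT of the cohort. In Ripk1 D138N 5xFAD against 5xFAD the member medians were -1.72 for the interferon response and -0.18 for disease-associated microglia; in Zbp1 KO 5xFAD against 5xFAD they were -0.79 and -0.96.

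The effect of the mutation on interferon genes depended on the transgenes. The 5xFAD effect on the D138N background was smaller than on the WT background for Isg15 (interaction -2.73 ± 0.31, edgeR, adjusted p = 0.012), Irf7 (-2.59 ± 0.36, 0.0404), Ifit1 (-2.51 ± 0.36, 0.0404), Oasl2 (-2.72 ± 0.4, 0.0404) and Irgm1 (-1.51 ± 0.19, 0.0261). They are among the 6 genes called by edgeR (0 higher). DESeq2 called 75, of which 18 were higher and 57 lower. The interferon list was lower as a whole (median -1.77, 38 of 39 adjusted over the list alone; adjusted p = 0.00256 with an estimated correlation). Inflammatory cytokines and NF-kB targets were lower as a list (-0.5, 2 of 25 adjusted over the list alone, 0.0272), while antigen presentation (-1.28, 13 of 22 over the list alone) was not once the correlation was estimated (adjusted p = 0.0744). The 6 became 0 without WT 1, WT 3, 5xFAD 3 or Ripk1 D138N 5xFAD 3, 1 without WT 2, Ripk1 D138N 1 or Ripk1 D138N 5xFAD 1, 2 without 5xFAD 1 or Ripk1 D138N 2 and 3 without Ripk1 D138N 3. They became 11 without 5xFAD 2 and 31 without Ripk1 D138N 5xFAD 2 (14 higher and 17 lower), and 0 with the Thy1 level as a covariate. In mice without the transgenes, D138N against WT had 0 of 21376 genes called by edgeR (514 at unadjusted p under 0.05, 0 by DESeq2, 1 without WT 3). The interferon list had a median of 0.03 there, and no list was called with an estimated correlation (myelin -0.19, adjusted p = 0.742).

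Microglial activation by 5xFAD persisted on the D138N background. Against D138N without the transgenes, Cst7 rose by 8.81 ± 0.31 (52 ± 7.45 CPM, edgeR, adjusted p = 4.34e-09), Itgax by 6.4 ± 0.3 (4.36e-08) and Clec7a by 5.49 ± 0.37 (8.93e-07). Gpnmb rose by 2.91 ± 0.14 (4.36e-08), C4b by 2.74 ± 0.12 (1.54e-08) and Gfap by 2.4 ± 0.15 (4.74e-07). Disease-associated microglia had 25 of 29 genes higher (27 adjusted over the list alone; median 1.54), homeostatic microglia 11 of 20 (15, 0.79) and lysosome 21 of 30 (22, 0.79). The interferon response was still raised, though in 18 of 39 genes (30 adjusted over the list alone; median 1.04, adjusted p = 0.00985 with an estimated correlation), as was antigen presentation (10 of 22, 20, 1.36). Myelin genes were higher in 14 of 20 (all 20 adjusted over the list alone; median 0.66, Mag 0.89 ± 0.14, Opalin 0.96 ± 0.17, adjusted p = 0.029 with an estimated correlation), but the interaction did not show the list to differ between backgrounds (0.34, 0.304). edgeR called 666 genes higher and 55 lower (DESeq2 1211 in all, 932 and 279). The 721 were 438 without Ripk1 D138N 3. The lower genes were 3 without Ripk1 D138N 1 or Ripk1 D138N 3 and 166 without Ripk1 D138N 2. Of the 666, 574 were higher in 5xFAD against WT too (54 by chance). Over the 636 genes raised in 5xFAD of the Zbp1 cohort, the median 5xFAD effect was 1.39 on the WT and 1.03 on the D138N background, smaller for 463 of them (72.8%).

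Loss of Zbp1 in 5xFAD gave lower point estimates for microglial genes at large, with no single gene called by edgeR in the fit of all libraries. C1qb was at 93.1 ± 7.98 CPM against 211 ± 63.9 in 5xFAD (-1.18 ± 0.18, edgeR, adjusted p = 0.112), Trem2 at 54.9 ± 6.26 against 128 ± 46.3 (-1.22 ± 0.22, 0.116), Ctss at -0.94 ± 0.17 (0.116) and Gpnmb, a gene of lipid-laden microglia, at -1.38 ± 0.25 (0.121). edgeR called 0 of 21274 genes, with 1875 at unadjusted p under 0.05, where DESeq2 called 3 higher and 148 lower. edgeR called 1 without 5xFAD 1 and 82 without 5xFAD 3, the 5xFAD library lowest in Cst7. Among the 82 were Trem2 (-1.5), C1qa (-1.38) and Gfap (-0.91). As lists these genes were lower with an estimated correlation: disease-associated microglia (median -0.96, 0 of 29 called, 24 lower adjusted over the list alone), homeostatic microglia (-0.73, 16 of 20) and the type I interferon response (-0.79, 22 of 39). So were lysosome (-0.59, 22 of 30), complement (-0.53, 7 of 19) and disease-associated oligodendrocytes (-0.55, 8 of 11), and all 6 lists had adjusted p = 0.0276. With the Thy1 level as a covariate the median over the 49 disease-associated and homeostatic genes went from -0.81 to -0.43. Antigen presentation (-0.76, 9 of 22 over the list alone), reactive astrocytes (-0.59, 7 of 27), cell death (-0.39, 3 lower and 1 higher of 26), inflammatory cytokines (-0.59, adjusted p = 0.0327) and oligodendrocyte precursors (-0.27, 0.0463) followed. Myelin (-0.29, adjusted p = 0.187 with an estimated correlation) and synapse (0.16, 0.107) were not called at that setting.

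Without the transgenes Zbp1 KO did not differ from WT by these tests, and the interaction was not shown. In KO against WT edgeR called 0 genes (779 at unadjusted p under 0.05, 1 by DESeq2) and no list held with an estimated correlation, with disease-associated microglia at a median of -0.34 (adjusted p = 0.456). For the interaction edgeR called 0 genes (480 at unadjusted p under 0.05, 0 by DESeq2), and the interferon response (-0.72) and antigen presentation (-0.75) had adjusted p = 0.126 each with an estimated correlation, disease-associated microglia (-0.4) 0.272. 5xFAD still raised glial genes in KO animals: Cst7 by 8.24 ± 0.95 (33.5 ± 7.33 CPM, edgeR, adjusted p = 0.000365), Clec7a by 6.75 ± 0.77 (0.000323), Trem2 by 2.46 ± 0.23 (0.000115), C4b by 2.45 ± 0.16 (6.13e-06) and Oasl2 by 1.5 ± 0.21 (0.00158). Disease-associated microglia had 19 of 29 genes higher (24 adjusted over the list alone; median 1.5), the interferon response 6 of 39 (22, 0.91) and antigen presentation 12 of 22 (18, 1.29). Interneuron genes (median -0.39, 6 of 15 lower over the list alone; adjusted p = 0.0149 with an estimated correlation) and neocortical genes (-0.43, 4 of 14, 0.0149) were lower as lists. edgeR called 252 genes higher and 9 lower (DESeq2 495 in all), and the 261 fell to 123, 152 and 164 without KO 1, 2 and 3 and to 157, 136 and 168 without KO 5xFAD 1, 2 and 3. Of the 252, 246 were higher in 5xFAD against WT (7.56 by chance). Over the 1714 genes raised in 5xFAD of the Ripk1 cohort the median 5xFAD effect was 0.54 on the WT and 0.29 on the KO background, smaller for 1430 of them (83.4%).

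Genes defined in 1 cohort and tested in the other moved the same way for each mutation. The p-values of these outside lists are from camera with an estimated correlation and are not adjusted over the lists. The 636 genes higher in 5xFAD of the Zbp1 cohort had a median of -0.222 in Ripk1 D138N 5xFAD against 5xFAD (-0.003 for other genes). Of them 509 (80%) were down and 55 called lower (unadjusted p = 0.00243). The 1714 genes higher in 5xFAD of the Ripk1 cohort had a median of -0.451 in Zbp1 KO 5xFAD against 5xFAD, with 1634 (95.3%) down (unadjusted p = 0.00444). The 1712 lower genes had 0.182 with 1565 up (unadjusted p = 0.0418). The 27 genes lower in the Zbp1 cohort had 0.128 under Ripk1 D138N, with 20 up and no call once the correlation was estimated (unadjusted p = 0.141). Effects of 5xFAD and of the mutation share the 5xFAD libraries, which alone gives a negative correlation. For Ripk1 D138N this was -0.668 against -0.526 in simulations without any genotype effect, for Zbp1 KO -0.49 against -0.483. The covariance went beyond the simulations in both cohorts, with -0.192 against -0.071 (-0.075 to -0.068) for Ripk1 D138N and -0.168 against -0.104 (-0.11 to -0.099) for Zbp1 KO. The share of genes with opposite signs did so for Ripk1 D138N only (78.3% against 67.2%; 65.6% against 66.3% for Zbp1 KO). For Zbp1 KO these measures disagree. In both cohorts the simulations lack the 5xFAD effect and draw each gene on its own, so their range leaves out variation that genes of a library share. By these measures it stays open in each cohort whether shared libraries alone explain the opposition.

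The lists lowered differed between the cohorts, in which mutation and cohort cannot be separated. Tested as a difference of the mutant effect in 5xFAD between cohorts, edgeR called 0 of 22565 genes (1064 at unadjusted p under 0.05, 8 by DESeq2, and 8 by edgeR without 5xFAD 3 of the Zbp1 cohort). Isg15 had -1.79 ± 0.37 and Gpnmb 1.47 ± 0.3, each with adjusted p = 0.524. The interferon response fell further in the Ripk1 cohort (median difference -0.71, 12 of 39 with p adjusted over the list alone; adjusted p = 0.0119 with an estimated correlation), and oligodendrocyte precursor genes in the Zbp1 cohort (0.4, 2 of 10, 0.0155). Interferon scores of the 5xFAD libraries, relative to WT of the cohort, were 2.475 to 3.063 (Ripk1) and 1.794 to 1.99 (Zbp1). Those of the mutant 5xFAD libraries overlapped, at 0.988 to 1.22 and 0.968 to 1.169. The scores depend on the WT libraries of each cohort, which ran from -0.137 to 0.106 (Ripk1) and from -0.299 to 0.5 (Zbp1). Which genotype holds the difference between cohorts was not tested. Disease-associated microglia (0.6, 10 of 29 over the list alone), homeostatic microglia (0.61, 9 of 20) and lysosome (0.41, 13 of 30) leaned toward a larger fall in the Zbp1 cohort without passing (adjusted p = 0.053, 0.053 and 0.0623 with an estimated correlation).

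RNA in the ZBP1 IP was compared with input in 1 library each from WT and 5xFAD, so there is no replicate check and intervals cover counting error only. No control IP is analysed here, and the largest ratios below were higher in WT, where hippocampal Zbp1 was nearly silent, than in 5xFAD. Satellite repeats went the other way, but mostly through the input, where their share was 2.69% in WT and 1.6% in 5xFAD against 3.44 and 3.67% in IP. Neither direction shows or excludes binding by ZBP1. The highest genes with at least 100 counts included several short structured noncoding RNAs and ribosomal RNA, a grouping made after the values were seen. Rn7sk had a log2 ratio of IP to input of 4.41 in WT and 3.24 in 5xFAD, Rmrp 4.28 and 2.22 and Rpph1 3.87 and 2.51. Rn18s was at 4.04 (4 to 4.09) and 2.81, and Mir6236, which overlaps ribosomal sequence, at 5 (4.57 to 5.7) and 3.57 (3.24 to 4.03). Lars2, whose transcript holds sequence like that of ribosomal RNA, was at 4.57 (4.46 to 4.69) and 3.24, and the nuclear RNA Malat1 at 3.32 (2.97 to 3.78) and 2.5. The messenger RNA Alb, which encodes serum albumin, was among the highest in 5xFAD, at 2.61 (2.11 to 3.34) in WT and 2.35 (1.86 to 3.06) in 5xFAD. Zbp1 itself was at 1.58 (0.96 to 2.4) and 1.39 (0.75 to 2.23), from 26 counts in input and 53 in IP of WT and from 25 and 50 in 5xFAD. Ripk1 was near input (0.19 and 0.16), as was App (-0.49 and 0.06). In the input Thy1 had 13 counts in WT and 1131 in 5xFAD, which carries the Thy1 cassette. Of 17696 genes with at least 20 counts 24 had a ratio of at least 2-fold in both genotypes. Between genotypes 2131 differed by at least 2-fold, and the ratios correlated weakly (r = 0.17, 0.45 at 100 counts or more), so single-gene ratios at low counts carry little information.

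Among lists, small nucleolar RNAs (4 genes, median 2.01 in WT and 0.84 in 5xFAD) and the small nuclear and 7S RNAs (3 genes, 3.04 and 1.02) lay above all matched random lists in each genotype. The interferon response (-0.01, percentile 97.3, and -0.3, 82.4), disease-associated microglia (0.14, 99.9, and -0.36, 63.9) and histone genes (0.01, 97.7, and -0.33, 84.4) were placed higher in WT than in 5xFAD, but the difference between genotypes itself was at percentiles 11.3, 13 and 13.8 of matched random lists. Synapse genes (-0.23, 8.3, and -0.17, 99.5) were at percentile 99 of that difference. Ribosomal protein genes stayed in the middle (-0.26, 23.2, and -0.51, 18.3). Repeats took 91 to 92.4% of the counts of each library, mostly LINE (36.5 to 39.6%), LTR (26 to 27.3%) and SINE elements (19.9 to 22%) with shares alike in input and IP. Satellites, at 1.6 to 3.67%, were higher in IP by 0.36 in WT and 1.19 in 5xFAD.

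**Figure D2:**
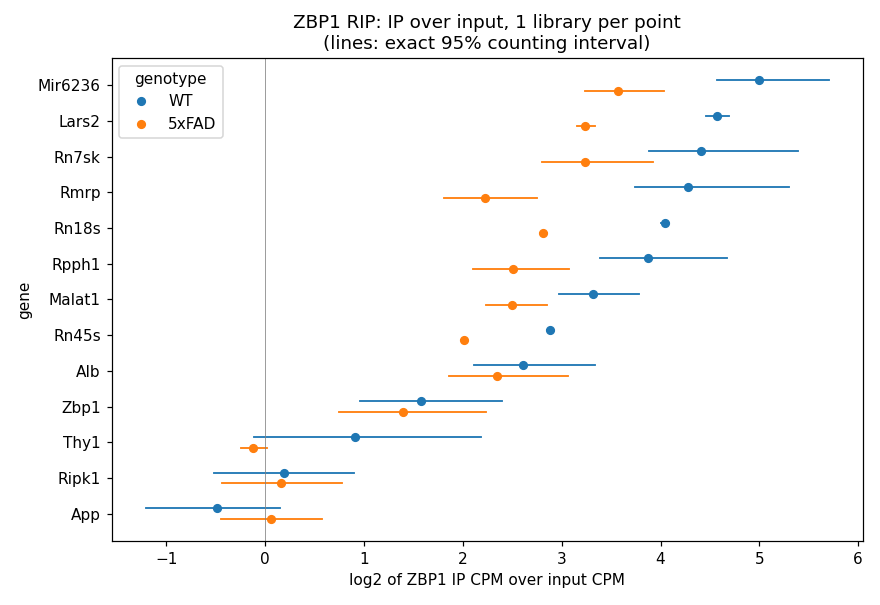
Log2 ratio of ZBP1 IP to input for the genes highest in either genotype and for Zbp1, Ripk1, App and Thy1, with exact 95% counting intervals. Rn7sk was at 4.41 (WT) and 3.24 (5xFAD), Zbp1 at 1.58 and 1.39, and Ripk1 at 0.19 and 0.16.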

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

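The comparison of interferon with homeostatic genes, the source of the RIP reads, the satellite repeat and the difference of the mutant effect between cohorts were chosen after the values were seen; the Thy1 covariate, the removal of low-Malat1 libraries and the splits of libraries were written down before their own results were seen.

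Differences between groups that a test of the difference called are these. The interaction of 5xFAD with Ripk1 D138N called 6 genes, and in it the interferon response (median -1.77) and inflammatory cytokines and NF-kB targets (-0.5) were lower. Between cohorts the interferon response differed in its 5xFAD effect (0.98) and in the mutant effect (-0.71), and oligodendrocyte precursor genes differed in the mutant effect (0.4). Outside the gene counts, the major satellite repeat GSAT_MM was higher in ZBP1 IP than in input by 0.42 in WT and 1.56 in 5xFAD, with 1 library each. The 5xFAD ratio rests on a low input as well, since GSAT_MM had 96064 counts in input and 203589 in IP of 5xFAD against 187106 and 161249 in WT, and the cause was not tested.

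Interferon genes were lower in Ripk1 D138N 5xFAD than in 5xFAD, and the transgene promoter gene Thy1 was lower there by -0.41 ± 0.12. edgeR did not call Thy1, though the authors' deposited comparison lists an adjusted p of 0.0344 for it. With Thy1 as a covariate the median of the interferon list went from -1.72 (member SD 0.63) to -1.48 (0.62). By edgeR 0 instead of 30 of 39 members were called, but 37 had an unadjusted p under 0.05 (39 without the covariate). The calls ended as the fold shrank and the median SE of a member grew from 0.27 to 0.42. The smallest adjusted p (edgeR) was 0.441 after 0.000383. The median with Thy1 met the threshold written beforehand against lower transgene expression, but not by more than the members' SD. That margin was not part of the written rule. Lower transgene expression could still be part of the cause, and the question stays open. An even loss of microglia would have lowered homeostatic genes as much. Their median (-0.12) lay 1.59 above that of the interferon genes, more than the spread of the members. A loss of only some microglia was not tested. As a hypothesis that was not tested here, RIPK1 kinase activity could feed the interferon response, which animals matched for transgene expression or a RIPK1 kinase inhibitor given to 5xFAD mice would test.

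Microglial genes were lower in Zbp1 KO 5xFAD than in 5xFAD at a median of -0.81 over the 49 disease-associated and homeostatic genes. With Thy1 as a covariate the median was -0.43, which neither removes the pattern nor leaves it clear of lower transgene expression. Without the libraries low in Malat1 it was -0.7. This met the threshold written beforehand against that explanation, but not by more than the members' SD (0.37). That margin was not part of the written rule. How much libraries that stand apart could explain is left open, and this median was not computed without the others that stood apart. Less microglial activation without ZBP1 is a hypothesis. With all libraries edgeR called no single gene in this contrast, where DESeq2 called 3 higher and 148 lower. More animals matched for transgene expression would test the hypothesis.

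RIP gene counts were unlike hippocampal mRNA: in WT input Ttn had 967 counts and Camk2a 50, where WT hippocampus had 4.86 and 4250 CPM (examples chosen after the values were seen). Counts in WT input correlated with genomic gene length (rho 0.67) about as well as with hippocampal CPM (0.62), a difference of 0.05 over 22878 genes. Reads from genomic DNA or unspliced RNA could give such counts. The comparison cannot tell, because the difference is small and CPM, which are not corrected for gene length, can follow length themselves. In WT input 91.8% of all counts lay in repeats. No biological explanation was tested for it.

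With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Counts of calls, real and highest other, were 3449 and 0 for 5xFAD against WT in the Ripk1 cohort, 78 and 7 for Ripk1 D138N 5xFAD against 5xFAD, 0 and 40 for Ripk1 D138N against WT, 721 and 0 for Ripk1 D138N 5xFAD against Ripk1 D138N, 0 and 1 for Zbp1 KO 5xFAD against 5xFAD, 0 and 0 for Zbp1 KO against WT, and 261 and 1 for Zbp1 KO 5xFAD against Zbp1 KO. For the outside lists the medians were -0.222 and 0.177, 0.128 and -0.089 (Ripk1 D138N), -0.451 and -0.351, and 0.182 and 0.171 (Zbp1 KO). In the Zbp1 cohort 5xFAD against WT called 665 genes, and a split with WT 1, 5xFAD 1 and 5xFAD 3 together called 592. That split put the low-Malat1 libraries WT 2 and 5xFAD 2 on its other side. A structure of the samples is possible, but the 592 genes were not examined. The split of D138N and WT with 40 calls put WT 1, WT 3 and D138N 3 together. These libraries had the lowest choroid plexus scores (-0.107, -1.558 and -2.594 against 1.664, 2.067 and 2.162). Neighbouring tissue could be another structure, but the 40 genes were not examined, so this was not tested. For the Ripk1 interaction 2 of 100 splits, the real one included, called as many as the 6 genes or more (highest other 52). These splits shuffled all genotype labels of the cohort and so mixed carriers with non-carriers within a group. Their share therefore cannot say how unusual the interaction is. For the Zbp1 interaction, the difference of the 5xFAD effect and that of the mutant effect the real count was 0, so that 100 of 100 splits were as large was fixed in advance and says nothing about chance. Their highest other counts were 52, 4407 and 290, and since such splits can carry the 5xFAD or mutant effect itself into the difference, no hidden structure needs to be assumed.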

How the results depend on the processing

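The Thy1 and choroid plexus covariates and the removal of the low-Malat1 libraries were added after the data were seen, and the sex covariate was not run because all 24 libraries show a male pattern. Between carriers and non-carriers of the transgenes only the count of calls with Thy1 was kept, because Thy1 follows the transgenes; gene and list values for those contrasts were dropped after they were seen. The cause of a changed result was not tested.

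Without a filter, calls were 387 for Ripk1 D138N 5xFAD against 5xFAD, 2 for D138N against WT and 145 for the Ripk1 interaction. They were 1030 for 5xFAD against WT of the Zbp1 cohort, 498 for Zbp1 KO 5xFAD against 5xFAD, 94 for KO against WT, 628 for KO 5xFAD against KO, 29 for the Zbp1 interaction, 188 for the difference of the 5xFAD effect between cohorts and 68 for the difference of the mutant effect in 5xFAD between cohorts. DESeq2 gave 278, 1211 (D138N 5xFAD against D138N), 75, 1034, 151, 1, 495, 26 and 8 for those it moved by more than 1.5 times or from 0, and 4284 for 5xFAD against WT of the Ripk1 cohort. Only the 6 libraries compared gave 339 for 5xFAD against WT of the Zbp1 cohort, 2 for KO against WT and 877 for KO 5xFAD against KO. Thy1 as a covariate gave 0 for 5xFAD against WT in each cohort, 0 for Ripk1 D138N 5xFAD against 5xFAD, 2 against D138N, 0 for the Ripk1 interaction and 0 for KO 5xFAD against KO. Without the low-Malat1 libraries the Zbp1 cohort gave 1121 (5xFAD against WT), 4 (KO 5xFAD against 5xFAD) and 583 (KO 5xFAD against KO). With an estimated correlation 71 instead of 157 list results were called, and the 27 genes lower in the Zbp1 cohort (0.128) were not (camera, unadjusted p = 0.141). For the RIP libraries, genes at 2-fold in both genotypes were 43 with TMM factors and 9 with 100 counts instead of 24, and those that differed were 57 instead of 2131 at 100 counts.

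As a block the replicate number gave 0 for the Ripk1 interaction and 41 for KO 5xFAD against 5xFAD. Residuals of libraries with the same number correlated at -0.22 to 0.24 (Ripk1) and -0.11 to 0.4 (Zbp1), and only 5 and 6 of 18 such pairs were above 0.1, so numbers were not taken as pairs. As a hint that the number marks something shared, 8 and 9 of 12 libraries correlated best with their own number.

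Leaving out 1 library gave 1757 to 3293 calls for 5xFAD against WT, 14 to 673 for D138N 5xFAD against 5xFAD, 0 to 1 for D138N against WT, 438 to 741 for D138N 5xFAD against D138N and 0 to 31 for the interaction in the Ripk1 cohort. In the Zbp1 cohort it gave 413 to 1103, 0 to 82, 0 to 0, 123 to 168 and 0 to 0 in that order. Outside lists ran from -0.289 to -0.181 and from 0.105 to 0.162 (D138N) and from -0.566 to -0.3 and from 0.108 to 0.256 (KO), and the cohort differences from 0 to 593 and from 0 to 8. Signs turned for neocortex in D138N 5xFAD against 5xFAD with Thy1 (-0.14) and, with 1 library left out, for Fosb in 5xFAD against WT (-0.58 to 4.98, lowest without 5xFAD 1). Immediate early genes between cohorts ran from 0.02 (without 5xFAD 1 of the Ripk1 cohort) to 2.09. Oxidative phosphorylation in KO 5xFAD against 5xFAD was 0 without the low-Malat1 libraries and -0.43 to 0.02 with 1 left out (highest without 5xFAD 2). Choroid plexus in KO against WT was 0.94 without the low-Malat1 libraries and -2.09 to 0.94 with 1 left out (highest without WT 2). In the Zbp1 interaction it was -1.4 without the low-Malat1 libraries and -1.19 (without WT 2) to 1.91 with 1 left out, and 0.41 without 5xFAD 1. Of single-gene results 19722 were the same, 552 stronger, 466 weaker, 9 moved and 1 reversed, and of list results 4307, 214, 240, 0 and 9.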

Other observations

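No test in this part was chosen before its result was seen. In the authors' deposited table of 5xFAD against WT in the Ripk1 cohort 715 genes are marked up and 96 down of 18096 listed, and in that of the Zbp1 cohort 554 and 17 of 17994. The authors' deposited table of 5xFAD over Ripk1 D138N 5xFAD marks 159 genes up and 47 down, and that of 5xFAD over Zbp1 KO 5xFAD marks 252 up and 8 down, with Zbp1 at 2.9 and an adjusted p listed as 1. In the authors' deposited table of RIP IP over input, 23 entries are marked up and 1 down in WT, and 21 and 2 in 5xFAD.

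In RIP input of WT and 5xFAD Ttn (967 and 1132 counts), a long gene of muscle, stood above Snap25 (38 and 26) and Apoe (23 and 28), which are abundant in brain; these examples were chosen after the values were seen.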
